A study of Homo sapiens with 16 samples.

How the data were processed

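Poly(A) RNA was sequenced in 16 libraries of NCI-H1299, a human non-small cell lung carcinoma line without p53, and of NCI-H1299 stably expressing the p53 Y220C mutant. Each line was exposed for 24 h to MS78 at 10 µM or to its vehicle DMSO, giving 4 groups of 4 libraries. The groups were taken from the sample labels and are called Null DMSO, Null MS78, Y220C DMSO and Y220C MS78 with the replicate numbers of the labels. Per the labels, the p53-Y220C line was kept in medium with G418 and the p53-null line was not, so line, G418 and transgene cannot be told apart in any comparison of the lines. The labels do not state whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

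The deposited tables hold 1 line per transcript and have the columns that Salmon writes. Estimated counts of reads per transcript, which need not be whole, were made by the authors and were not normalized, per the file headers. The TPM values were scaled by the authors to the effective transcript length and to a common library sum, per the file headers. The transcript length and the effective transcript length in other columns were also given by the authors, per the file headers. Read quality was examined with FastQC 0.11.8 and the genome build was hg38, per the submitters' processing notes. The version of the quantifier, the transcript annotation, trimming and bias options are not given in the sources used here.

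Each table listed 197653 transcripts, of which 193348 (97.82%) matched a transcript of GENCODE 29 (GRCh38) by identifier without version. Estimated counts of matched transcripts were summed per gene into 56865 genes and rounded to whole numbers. Unmatched transcripts held 0.278% to 0.325% of the reads of a library and were left out, and coordinates are those of GENCODE 29. Total estimated reads were between 20.3 M and 27.7 M per library. A gene with 0 reads in a library can have up to 3 reads' worth of signal at that depth, and such floors cover counting error only. The quantifier divides reads between transcripts of similar sequence, so values of EIF3CL, CKMT1B, HSPA1A, HSPA1B, HSPA6, PCDHA12, PCDHGA5, RFPL4A, H4C8, NME1 and MT1X, which have close copies, are uncertain. The sources used here do not say whether the counting used strand.

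Genes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F-tests after filterByExpr with its default settings and TMM normalization, in 1 fit of the 16 libraries with 1 mean per group and 12 residual degrees of freedom. Of the 56865 genes, 15687 passed the filter and were tested. The 4 comparisons were MS78 against DMSO in p53-null cells, MS78 against DMSO in p53-Y220C cells, the difference of these responses (the interaction of line and treatment), and p53-Y220C against p53-null cells under DMSO. P-values were adjusted over all genes tested by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and are adjusted p-values of edgeR's quasi-likelihood test wherever a gene's adjusted p is printed. Levels are CPM (reads as a fraction of the TMM-scaled library total, times 1e6), given as mean ± SD over 4 libraries. SE is an approximate standard error, the size of a log2 fold change divided by the square root of its F statistic. It is least reliable for genes with few reads.

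Before the data were examined, 27 gene lists were fixed: 21 pathway or function lists, markers of 4 other cell types, and 2 lists for RNA quality (mitochondrially encoded genes and ribosomal protein genes). Of their members, 3 had no gene in the annotation. The histone list holds replication-dependent histone genes, and how far poly(A) RNA represents their transcripts was not tested. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 27 lists within a comparison. Counts of members that passed are given over all genes tested and after adjustment over the list alone. The rule for named genes was fixed at the same time. It took CDKN1A, MDM2, TNFRSF10A, TNFRSF10B, TNFRSF10C and TNFRSF10D whatever their values. It took the 6 rising and 6 falling protein-coding genes with the largest log2 fold change past an adjusted p of 0.05, a mean of at least 1 CPM in the compared groups and, in comparisons of 2 groups, no overlap between them. From each list it took up to 4 members past 0.05 with the largest log2 fold change and at least 1 CPM, or up to 2 where none passed. Some genes that the rule took or that counts of 5 or fewer hold are not reported here. Apart from these the text names fewer than the rule allows, in rank order, and how many are named for the difference between the lines was set after the alternatives had been seen. Genes named to spell out a count of 5 or fewer list members were chosen after their values were seen.

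The gene tests and list tests were tested on simulated counts drawn from the real means and library sizes for 15447 genes, with 118 genes changed 1.5-fold and 100 changed 2-fold in Y220C MS78 alone. For MS78 in p53-Y220C cells, 83.9% of the 1.5-fold and 94% of the 2-fold changes were recovered, and 2.53% of the calls were false. For the difference between the lines, 72.9% and 85% were recovered and 1.72% of the calls were false. In the other 2 comparisons, in which nothing had been changed, 0 genes were called. The list that held the changed genes was called for MS78 in p53-Y220C cells (camera adjusted p = 4.63e-81) and for the difference (3.35e-67). Of the other lists, 1 was called for MS78 in p53-Y220C cells. For the lines under DMSO, where nothing had been changed, 1 was called, and in the other 2 comparisons 0 were. Genes were drawn independently, and libraries of a group differed only by size and random spread. These shares therefore need not hold for the real libraries.

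Alternatives chosen before the data were examined were RLE size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a filter of 1 CPM in 4 libraries, gene counts from length-scaled TPM (the only use of the TPM values and transcript lengths), a fit of the compared groups alone, the replicate number as a block, a 2-fold threshold, and leaving out each library in turn. For lists these were an estimated correlation, fry, the replicate block, the 1 CPM filter and leaving out each library. Reads of PTPRC, a leukocyte gene, were found in 8 of the 16 libraries after the data were seen. Therefore 3 alternatives were added: a term for the libraries with PTPRC reads (at least 10 reads), the 8 libraries with them alone, and the 8 without them alone. In these 2 sets each line has 1 library in 1 of its treatment groups, which is assumed to vary like the other groups. Also added after the data were seen was a block of the replicate number within each treatment, shared by the 2 lines, for the difference and the comparison of the lines. The 11 leukocyte markers shown beside PTPRC and most tests of explanations were also chosen after the data were seen. Tables were prepared and plots drawn with Python 3.11.15.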

Results

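Poly(A) RNA was sequenced from NCI-H1299 cells, a human non-small cell lung carcinoma line that lacks p53, and from NCI-H1299 cells stably expressing p53 Y220C, a structural mutant of the tumour suppressor p53. Each line received the vehicle DMSO or 10 µM MS78, a compound made to bring the acetyltransferases p300 and CBP to p53 Y220C, for 24 h. Each of the 4 groups held 4 libraries. Estimated reads were 22.5 M to 24.7 M per library in Null DMSO, 20.7 M to 27.7 M in Null MS78, 20.7 M to 23.2 M in Y220C DMSO and 20.3 M to 21.8 M in Y220C MS78. The 10 most abundant genes held 6.85% to 9.03% of the reads of a library. No library repeated another of its group, since replicates of a group differed by a chi-square per gene between 2.53 and 11.3. The first principal component (41.5% of the variance) separated the lines, with p53-null libraries between -42.3 and -32.1 and p53-Y220C libraries between 18.4 and 53.8.

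Leukocyte transcripts were present in 8 of the 16 libraries, namely replicate 1 of both DMSO groups and replicates 2, 3 and 4 of both MS78 groups. PTPRC, which encodes the leukocyte surface phosphatase CD45, had 55 to 99 reads in each of these libraries and 0 to 1 reads in each of the others. GZMB, which encodes the cytotoxic protease granzyme B, stood at 16.7 to 23.5 CPM in the former and had 0 to 1 reads in the latter. GNLY, which encodes the cytolytic protein granulysin, stood at 5.46 to 40.7 CPM in the former. PTPRC defined the 8 libraries, and the 11 other leukocyte markers examined, which were chosen after this was seen, had more reads in each of them than in any of the other 8. In a fit with a term for these libraries, 154 genes were called for the term, 151 of them higher where PTPRC had reads. Of 13 tested haematopoietic markers, 10, PTPRC included, were among them (median log2 difference 4.84, camera adjusted p = 1.36e-32, and adjusted p = 2.81e-06 with an estimated correlation). Because 1 of 4 DMSO and 3 of 4 MS78 libraries of each line held these reads, values within the 8 libraries with PTPRC reads and within the 8 without are given for CDKN1A, for the p53 target and TRAIL lists, for counts, and where a call of a named gene or a list was lost. The second principal component (20% of the variance) split the libraries the same way within each group. On it DMSO replicate 1 was the highest of its group, at 9.5 in p53-null and -10 in p53-Y220C cells, where the other DMSO libraries lay between -39.3 and -18.6. MS78 replicate 1 was the lowest of its group, at -0.5 and -6.5, where the other MS78 libraries lay between 23.9 and 34.8.

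**Figure D1:**
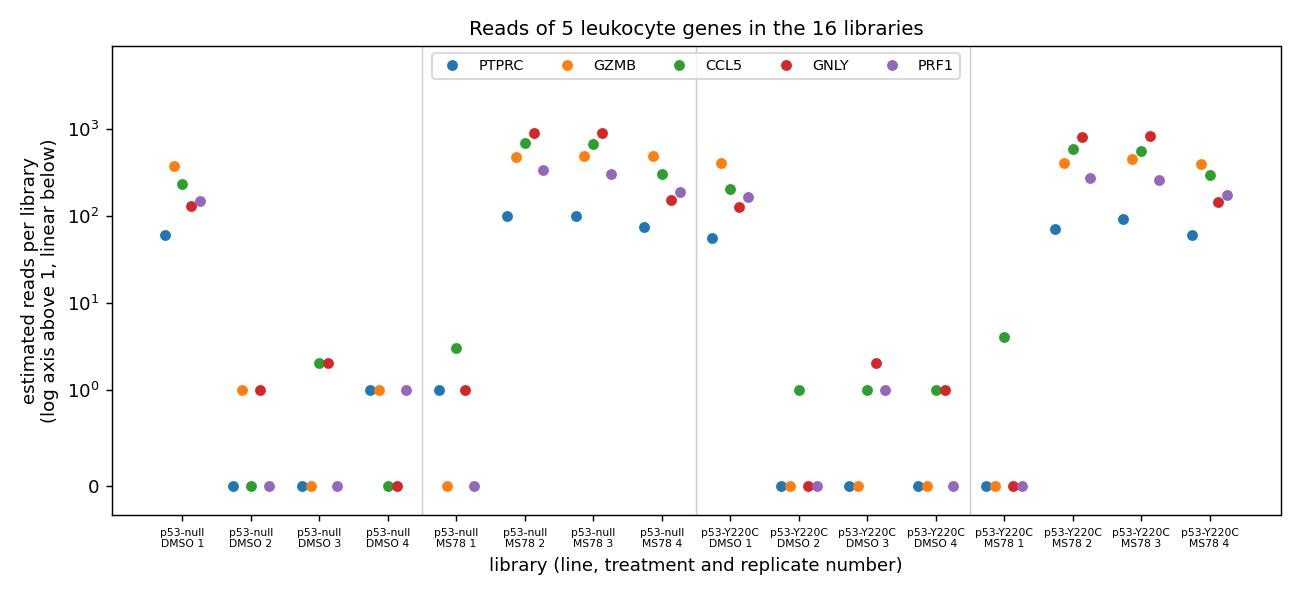
Estimated reads of PTPRC, GZMB, CCL5, GNLY and PRF1 in each of the 16 libraries, by line, treatment and replicate number, on an axis that is logarithmic above 1 read and linear below. Each point is 1 gene in 1 library, and PTPRC had 55 to 99 reads in 8 libraries and 0 to 1 reads in the others.

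**Figure D2:**
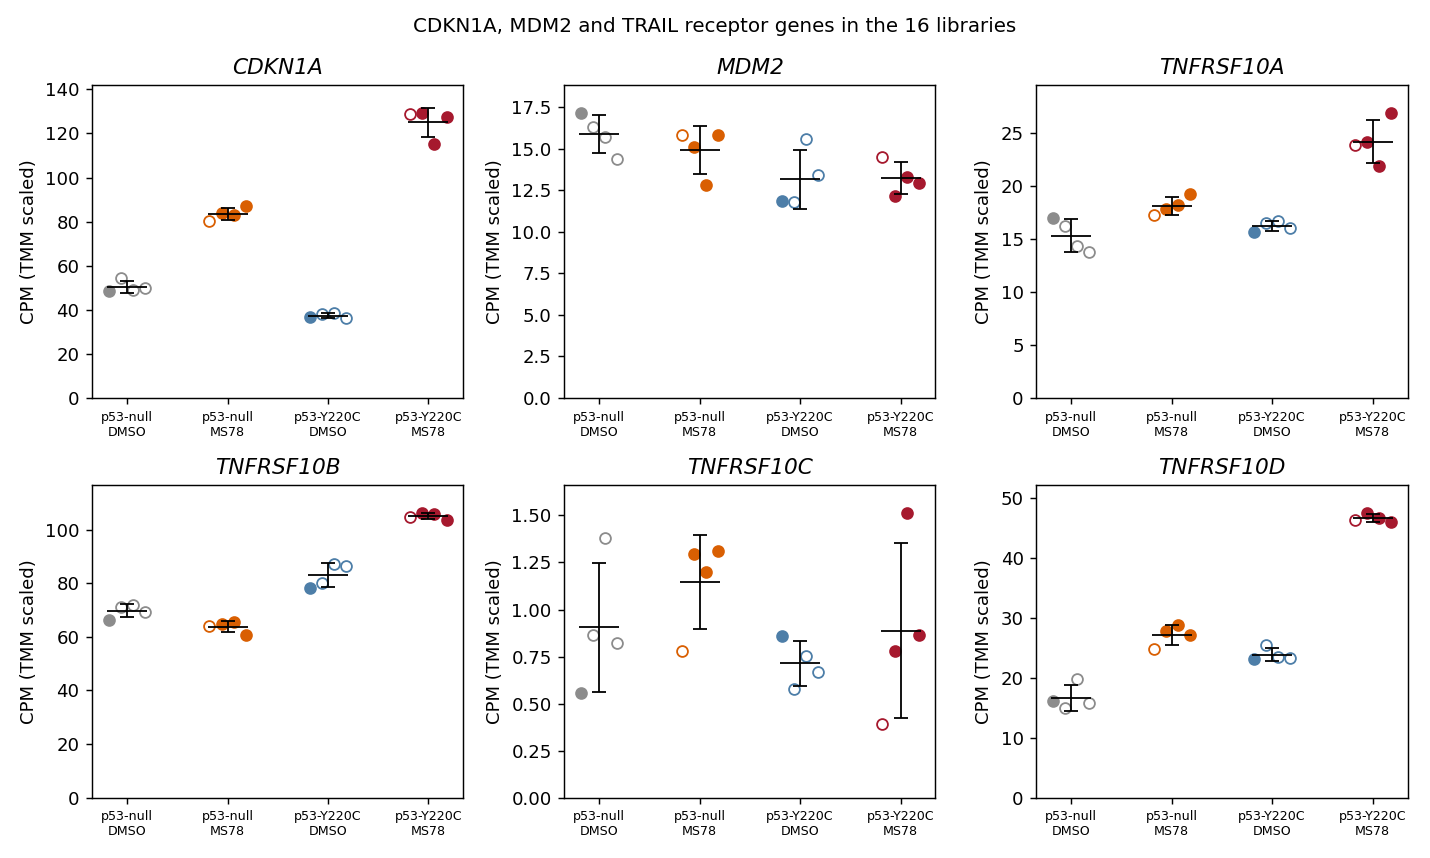
Levels of CDKN1A, MDM2, TNFRSF10A, TNFRSF10B, TNFRSF10C and TNFRSF10D in CPM, by group. Points are libraries (filled with PTPRC reads, open without) and bars are mean ± SD of 4 libraries, and CDKN1A rose from 37.4 to 125 CPM with MS78 in p53-Y220C cells.

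The response of p53-null cells to MS78 shows what the compound did without its intended target. Cholesterol synthesis genes rose, with the highest median of the 27 lists. HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512), which encodes HMG-CoA synthase, rose 10.4-fold from 72.0 ± 2.6 to 745 ± 58 CPM (SD, n = 4, log2 fold change 3.37, SE 0.05, adjusted p = 1.86e-20). MVD, the mevalonate decarboxylase gene, rose 9.87-fold from 71.7 ± 4.9 to 708 ± 33 CPM. Genes of DNA replication and mitosis fell together, and CDK1, the kinase that drives entry into mitosis, went from 108 ± 2.9 to 51.0 ± 1.4 CPM (log2 fold change -1.09, SE 0.04, adjusted p = 9.78e-15). Targets of the stress factor ATF4 fell too, with SLC7A11, the cystine transporter, at -1.14 (SE 0.07) and ASNS, which encodes asparagine synthetase, going from 814 ± 47 to 372 ± 31 CPM (-1.13, SE 0.05, adjusted p = 5.18e-13).

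Past the threshold were 4402 of the 15687 genes tested, 28.1% of them. Of these 2319 rose and 2083 fell, 213 changed at least 2-fold (162 up, 51 down), and the median size of the log2 fold change was 0.281. Within the 8 libraries with PTPRC reads 2346 genes were called and within the 8 without 1070, of which 2197 and 1053 were also called in the pooled test, with 0 in the opposite direction. Each set had a single library in 1 treatment group, MS78 in the set without PTPRC reads and DMSO in the other. Both sets are part of the pooled libraries, so shared calls and directions, here and in the other comparisons, are no independent check.

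Among the p53-related genes fixed by name, CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), which encodes the cell cycle inhibitor p21, rose in these cells without p53. It went from 50.5 ± 2.7 to 83.6 ± 2.7 CPM (1.66-fold, SE 0.05 on the log2 scale, adjusted p = 1.35e-10), with log2 fold changes of 0.79 and 0.65 within the sets with and without PTPRC reads. The decoy receptor gene TNFRSF10D (ENSG00000173530, chromosome 8, 23135588 to 23164030) rose 1.63-fold from 16.7 ± 2.1 to 27.2 ± 1.7 CPM (adjusted p = 7.54e-08). The TRAIL receptor gene TNFRSF10A (ENSG00000104689, chromosome 8, 23190452 to 23225126) stood at 0.24 (SE 0.07, adjusted p = 0.0139). That call was lost without Null DMSO 3 (0.0587) or Null DMSO 4 (0.0699), with length-scaled TPM (0.135) and within either set (0.667 and 0.338). The TRAIL receptor gene TNFRSF10B (ENSG00000120889, chromosome 8, 23020133 to 23069179) stood at -0.13 (SE 0.04, adjusted p = 0.0271). That call was lost without Null DMSO 2 (0.059), Null DMSO 3 (0.0612) or Null MS78 4 (0.0934), with length-scaled TPM (0.0746), with a term for PTPRC reads (0.103) and within either set (0.53 and 0.356). MDM2 (ENSG00000135679, chromosome 12, 68808176 to 68850686), which encodes the ubiquitin ligase of p53, was at 15.9 ± 1.1 and 14.9 ± 1.4 CPM (adjusted p = 0.5). TNFRSF10C (ENSG00000173535, chromosome 8, 23102590 to 23117437) was at 0.906 and 1.15 CPM (adjusted p = 0.515).

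Of 70 p53 target genes, 17 rose and 14 fell (18 and 17 adjusted over the list alone, median log2 fold change 0, camera adjusted p = 0.953). SESN2, a stress-induced gene that ATF4 also drives, was at -0.79 (SE 0.05). Of 24 TRAIL and death receptor genes 5 rose and 3 fell (TNFRSF10B, CFLAR and TRAF2), against 5 and 4 adjusted over the list alone (camera adjusted p = 0.837). Of 17 BCL2 family genes 5 rose (BCL2L2, BMF, BNIP3, BNIP3L and MCL1) and 2 fell (HRK and PMAIP1), the same counts adjusted over the list alone (camera adjusted p = 0.304). Members named to spell out counts of 5 or fewer, here and in the other comparisons, were chosen after their values were seen.

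Of 34 cholesterol synthesis and uptake genes, 29 rose and 4 fell, the same counts adjusted over the list alone (median 1.56, camera adjusted p = 1.01e-37). MSMO1, IDI1 and INSIG1, which act in this pathway or its control, rose 7.54-, 7.24- and 6.87-fold. The 4 that fell were ABCA1 (-1.22, SE 0.06) and ABCG1, which export cholesterol, MYLIP, which degrades the LDL receptor, and SREBF1, which encodes a regulator of lipid synthesis. Of 48 G2/M and mitosis genes all 48 fell, with 48 also adjusted over the list alone (camera adjusted p = 5.21e-46), and NDC80, a kinetochore gene, was at -0.94 (SE 0.04). Of 42 E2F, G1/S and replication genes 40 fell and 0 rose, the same counts adjusted over the list alone (camera adjusted p = 2.77e-40). CCNE2, a G1/S cyclin gene, was at -1.03 (SE 0.15), a call lost within the set with PTPRC reads (0.0637), and E2F2 was at -0.99 (SE 0.08). Of 72 DNA damage and repair genes 50 fell and 2, ERCC1 and RAD50, rose (53 and 2 adjusted over the list alone, camera adjusted p = 1.58e-20). RAD54L, which acts in homologous recombination, and the exonuclease gene EXO1 were at -1.07 (SE 0.05) and -1.02 (SE 0.09). Of 40 MYC target and ribosome biogenesis genes 26 fell and 0 rose (31 and 0 adjusted over the list alone, camera adjusted p = 5.03e-10). BOP1, a ribosome biogenesis gene, was at -0.36 (SE 0.08) and NME1 at -0.32 (SE 0.08), both lost within the set without PTPRC reads (0.263 and 0.19).

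Of 39 ATF4 targets of the integrated stress response, 32 fell and 1, KLHL24, rose (32 and 2 adjusted over the list alone, camera adjusted p = 3.17e-25). Autophagy and lysosome genes rose, 21 of 28, against 1, the protease gene CTSB, that fell (22 and 1 adjusted over the list alone, camera adjusted p = 1.73e-11). NEU1, a lysosomal sialidase gene, was at 1.40 (SE 0.04). Immediate early genes rose, 18 of 28, while JUN and MYC fell (19 and 3 adjusted over the list alone, camera adjusted p = 3.02e-08), with NR4A1 at 1.49 (SE 0.08) and EGR1 at 1.06 (SE 0.07). NRF2 and oxidative stress genes rose, 13 of 22, while GCLM and SLC7A11, both of glutathione synthesis, fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.000108). Of 28 hypoxia and glycolysis genes 18 rose and 1, VEGFA, fell (19 and 1 adjusted over the list alone). The camera adjusted p of that list was 1.39e-07, but adjusted p = 0.313 with an estimated correlation, and ALDOC (1.67, SE 0.31), an aldolase gene, missed the threshold within the set without PTPRC reads (0.0816). Of 30 interferon response genes 8 rose and 1, OAS3, fell, the same counts adjusted over the list alone (camera adjusted p = 0.0265, but adjusted p = 0.339 with an estimated correlation). That call was lost without Null MS78 4 (0.0823), with a term for PTPRC reads (0.107) and within the set without them (0.353). The interferon list was itself higher in the libraries with PTPRC reads (camera adjusted p = 0.00302, but adjusted p = 0.343 with an estimated correlation).

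Heat shock genes were not called as a list (7 of 18 rose and AHSA1 and HSPD1 fell, the same counts adjusted over the list alone, camera adjusted p = 0.206). Their median was -0.02 and their mean -0.04 against an upward test direction, and HSPB1, a small heat shock protein gene, was at 0.51 (SE 0.05). Of 25 ER stress genes 8 rose and HERPUD1 and HYOU1 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.155). NF-kB genes had a median of 0 and a mean of 0.08, and of 16 there rose ICAM1, LIF and RELB and fell CXCL2, IRF1, NFKBIA and SOD2 (3 and 4 adjusted over the list alone, camera adjusted p = 0.837). Among 31 genes of p300, CBP, BET and other chromatin regulators 7 rose and HDAC2, KAT2A and KAT7 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.333). The deacetylase genes HDAC9 and HDAC5 were at 1.38 (SE 0.07) and 0.73 (SE 0.04). EP300, which encodes p300, was at 0.30 (SE 0.08, adjusted p = 0.00968), a call lost without Null MS78 2 (0.0513) and within either set (0.0865 and 0.335). Of 33 TGF-beta and matrix genes 10 rose and SKIL, TGFBI and TNC fell (10 and 5 adjusted over the list alone, camera adjusted p = 0.304, median -0.01, mean 0.08), with the collagenase gene MMP1 at 1.83 (SE 0.09). Of 20 histone genes H2AC6, H2BC4, H2BC5, H2BC12 and H2BC21 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.354, median 0.01). Of 10 xenobiotic metabolism genes ABCB1, CYP1A1, CYP1B1 and TIPARP rose (4 adjusted over the list alone, camera adjusted p = 0.0688). The xenobiotic list passed without Null DMSO 4 (0.0345) or Null MS78 2 (0.0468), with the 1 CPM filter (0.0368), with a term for PTPRC reads (0.0378) and within the set with them (0.0422).

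Of 13 mitochondrially encoded genes MT-CO1, MT-CO3 and MT-ATP8 fell (2 adjusted over the list alone, median -0.12, camera adjusted p = 0.0481, but adjusted p = 0.477 with an estimated correlation). That call was lost without Null DMSO 2 (0.0624), Null DMSO 4 (0.115), Null MS78 3 (0.0874) or Null MS78 4 (0.126), with a term for PTPRC reads (0.193) and within either set (0.126 and 0.711). Of 61 ribosomal protein genes RPL19, RPL23, RPL23A and RPL34 rose (0 adjusted over the list alone, median 0.07, camera adjusted p = 0.00874, but adjusted p = 0.592 with an estimated correlation). Both of these lists, which reflect RNA quality, were lower in the libraries with PTPRC reads (camera adjusted p = 0.000364 and 1.03e-06, but adjusted p = 0.569 and 0.714 with an estimated correlation). Markers of other cells were not called. CDH1 of 8 epithelial markers (camera adjusted p = 0.354) and FBLN1 of 5 fibroblast markers (0.418) fell, and CD68 of 13 haematopoietic markers (0.172) and ELAVL3, INA and TUBB3 of 8 neural and HEK markers (0.241) rose. The counts were 1, 0, 1 and 3 adjusted over the list alone, and the haematopoietic list passed without Null DMSO 1 (0.0464) or Null MS78 1 (0.0269).

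Outside the lists, SNAI3, which encodes a zinc finger factor of the Snail family, had 2 to 11 reads under DMSO and 30 to 62 reads under MS78 (2.85, SE 0.39, adjusted p = 1.07e-05). EIF3CL fell by 2.20 (SE 0.48, adjusted p = 0.00151), a call lost within either set (0.0618 and 0.256). ARRDC4 and ULBP1 fell by 1.80 (SE 0.24) and 1.36 (SE 0.11) on the log2 scale, and CKMT1B fell by 1.28 (SE 0.26, lost within the set without PTPRC reads, 0.0895). TERT, the telomerase gene, fell by 1.26 (SE 0.32, adjusted p = 0.00511), a call lost with length-scaled TPM (0.064) and within either set (0.116 and 0.071).

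Exposure of p53-Y220C cells to MS78 tests the compound where its intended target is present. Heat shock genes rose together. HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910), which encodes a stress-inducible HSP70 chaperone, went from 4.64 ± 0.9 to 479 ± 17 CPM (103-fold, SE 0.07 on the log2 scale, adjusted p = 1.03e-23). HSPA1A, another HSP70 gene, went from 362 ± 17 to 4260 ± 84 CPM (11.8-fold, SE 0.04, adjusted p = 2.03e-23). CDKN1A rose 3.34-fold from 37.4 ± 1.2 to 125 ± 6.7 CPM (log2 fold change 1.74, SE 0.05, adjusted p = 4.51e-17).

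In all, 7611 of 15687 genes (48.5%) passed the threshold, 3913 up and 3698 down, with 696 at least 2-fold (372 up, 324 down) and a median size of 0.358. Within the libraries with PTPRC reads 5222 genes were called and within those without 3490, of which 4938 and 3368 were also called in the pooled test, with 0 in the opposite direction. Each set again had a single library in 1 treatment group.

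CDKN1A rose by 1.77 and 1.77 on the log2 scale within the sets with and without PTPRC reads. Of the 4 TRAIL receptor genes 3 rose. TNFRSF10A rose 1.49-fold (16.2 ± 0.46 to 24.2 ± 2.0 CPM, adjusted p = 8.68e-07), TNFRSF10B 1.27-fold (82.9 ± 4.5 to 105 ± 1.2 CPM, adjusted p = 7.15e-07) and TNFRSF10D 1.96-fold (23.9 ± 1.1 to 46.6 ± 0.6 CPM, adjusted p = 1.17e-10). TNFRSF10C had 8 to 29 reads in Y220C MS78 libraries (adjusted p = 0.515), and MDM2 was at 13.2 ± 1.8 and 13.2 ± 0.96 CPM (adjusted p = 0.952). Of 70 p53 target genes 31 rose and 12 fell, the same counts adjusted over the list alone (median 0.18, camera adjusted p = 0.00129, and 0.00169 and 0.00473 within the sets). LIF, a cytokine gene, and PGF, which encodes placental growth factor, were at 1.67 (SE 0.09) and 1.63 (SE 0.11). The smooth muscle actin gene ACTA2 stood at -2.43 (SE 0.79, adjusted p = 0.0151), a value that rested on Y220C DMSO 3, without which it was -1.69 (adjusted p = 0.096). It also missed the threshold within either set (0.702 and 0.0534). Of 24 TRAIL and death receptor genes 12 rose and 2 fell, namely CFLAR, which encodes the caspase-8 inhibitor FLIP, and DAP3. These counts were the same adjusted over the list alone (median 0.17, camera adjusted p = 0.00895, and 0.0286 and 0.0201 within the sets). BIRC3, an inhibitor of apoptosis, rose 2.0-fold and CASP9, the initiator caspase gene, was at 0.59 (SE 0.05). The ligand gene of this list, TNFSF10, and CSF1 of the p53 list were among the genes higher in libraries with PTPRC reads. Of 17 BCL2 family genes BAK1, BNIP3L, HRK, MCL1 and PMAIP1 rose and BAX fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.317). MCL1 was at 0.52 (SE 0.03), HRK at 0.44 (SE 0.11) and PMAIP1 at 0.39 (SE 0.08), and HRK missed the threshold within either set (0.11 and 0.101) and PMAIP1 within the set without PTPRC reads (0.132).

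Of 18 heat shock genes all 18 rose, with 18 also adjusted over the list alone (median 0.90, camera adjusted p = 4.8e-19). HSPA1B rose 9.75-fold, DNAJB1, an HSP40 co-chaperone gene, 4.58-fold from 290 ± 12 to 1330 ± 19 CPM, and BAG3, another co-chaperone gene, 4.22-fold. Of 25 ER stress genes 21 rose and 0 fell, the same counts adjusted over the list alone (camera adjusted p = 3.1e-13). HSPA5, the gene of the ER chaperone BiP, rose 2.91-fold from 956 ± 18 to 2780 ± 50 CPM. Immediate early genes rose, 22 of 28, against 1, PHLDA1, that fell, the same counts adjusted over the list alone (camera adjusted p = 1.34e-13). EGR4 and EGR2 went from 0 to 3 and 0 to 5 reads per library to 83 to 113 and 67 to 70 reads, so their fitted folds are uncertain. FOS, a subunit of the AP-1 factor, went from 5.28 ± 0.35 to 163 ± 8.5 CPM (30.9-fold, SE 0.08, adjusted p = 4.32e-21). NRF2 and oxidative stress genes rose, 17 of 22, while TALDO1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 9.68e-10), and HMOX1, which encodes heme oxygenase, rose 5.47-fold. NF-kB and inflammatory genes rose, 12 of 16, while CXCL2, SOD2 and TNFAIP2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.00053). The chemokine gene CCL2 was at 1.93 (SE 0.36) and PTGS2, the cyclooxygenase-2 gene, at 1.89 (SE 0.22). Among 39 ATF4 targets 11 rose and 20 fell (12 and 21 adjusted over the list alone, camera adjusted p = 0.199), with a median of -0.13, a mean of 0.03 and a downward test direction. The transcription factor gene ATF3 rose 4.91-fold from 9.13 ± 1.1 to 44.9 ± 2.5 CPM.

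Of 34 cholesterol genes 29 rose and 2, ABCA1 and SREBF1, fell, the same counts adjusted over the list alone (median 1.66, camera adjusted p = 1.88e-25). HMGCS1 rose 12.3-fold to 1320 ± 20 CPM and MVD 11.1-fold. Of 48 mitosis genes 47 fell and 1, CKS2, rose, the same counts adjusted over the list alone (camera adjusted p = 4.33e-31). The kinetochore gene SPC25 was at -1.66 (SE 0.06) and the proliferation marker MKI67 at -1.49 (SE 0.14). Of 42 replication genes 40 fell and 1, SLBP, rose (41 and 1 adjusted over the list alone, camera adjusted p = 4.89e-27), with E2F2 falling 3.54-fold and MCM5 at -1.51 (SE 0.05). Of 72 DNA damage genes 50 fell, and HUS1, LIG4, RNF168 and UIMC1 rose (52 and 4 adjusted over the list alone, camera adjusted p = 1.17e-12), with RAD54L falling 3.65-fold. Outside the lists RIBC2 and the kinetochore gene SPC24 each fell 3.95-fold.

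Autophagy and lysosome genes rose, 23 of 28, while CTSB fell (24 and 2 adjusted over the list alone, camera adjusted p = 5.33e-08). GPNMB was at 1.87 (SE 0.41, lost within the set without PTPRC reads, 0.0876) and NEU1 at 1.20 (SE 0.04). Of 20 replication-dependent histone genes 11 rose, and H2AC20 and H2BC9 fell, the same counts adjusted over the list alone (camera adjusted p = 0.00686). H4C8 rose 4.09-fold, from 18 to 28 reads per Y220C DMSO library to 67 to 98 per Y220C MS78 library. How far poly(A) RNA represents such transcripts was not tested. Of 28 hypoxia genes 16 rose, BHLHE40, a transcriptional repressor gene, 6.35-fold, and ENO1, GAPDH, LDHA, PGAM1 and TPI1, which encode glycolytic enzymes, fell. These counts were the same adjusted over the list alone (camera adjusted p = 0.00686, but adjusted p = 0.592 with an estimated correlation). Interferon genes rose in 18 of 30 cases, and IFI27, IFI35, ISG20, OAS3 and PSMB9 fell (19 and 6 adjusted over the list alone, camera adjusted p = 0.00628, but adjusted p = 0.168 with an estimated correlation). OASL and IFIT2 were at 2.31 (SE 0.28) and 1.99 (SE 0.08), and the interferon list was also higher in libraries with PTPRC reads (camera adjusted p = 0.00302, but adjusted p = 0.343 with an estimated correlation). Xenobiotic genes rose in 6 of 10 cases, and AHRR, the repressor of the aryl hydrocarbon receptor, fell, the same counts adjusted over the list alone (camera adjusted p = 0.03, but adjusted p = 0.168 with an estimated correlation). The metallothionein gene MT1X was at 1.61 (SE 0.11) and the efflux pump gene ABCB1 at 1.31 (SE 0.07).

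Among chromatin regulators 8 of 31 rose and 9 fell (8 and 11 adjusted over the list alone, camera adjusted p = 0.796, median -0.07, mean 0.04). HDAC9 rose 4.6-fold and HDAC10 was at -0.64 (SE 0.11). MYC targets were not called (12 rose and 15 fell of 40, 12 and 16 adjusted over the list alone, camera adjusted p = 0.787), and NME1, a nucleoside diphosphate kinase gene, fell 2.7-fold. TGF-beta genes were not called (10 rose and 8 fell of 33, the same counts adjusted over the list alone, camera adjusted p = 0.461, median -0.01, mean 0.09). Neither were mitochondrially encoded genes (6 rose and MT-CO1 fell of 13, camera adjusted p = 0.199) or ribosomal protein genes (RPL6, RPL23A, RPL37, RPLP1 and RPS27 rose and 8 fell of 61, camera adjusted p = 0.796, median 0.01, mean 0, downward test direction). Markers of epithelial, fibroblast, haematopoietic and neural or HEK cells had camera adjusted p = 0.796, 0.937, 0.332 and 0.816.

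**Figure D3:**
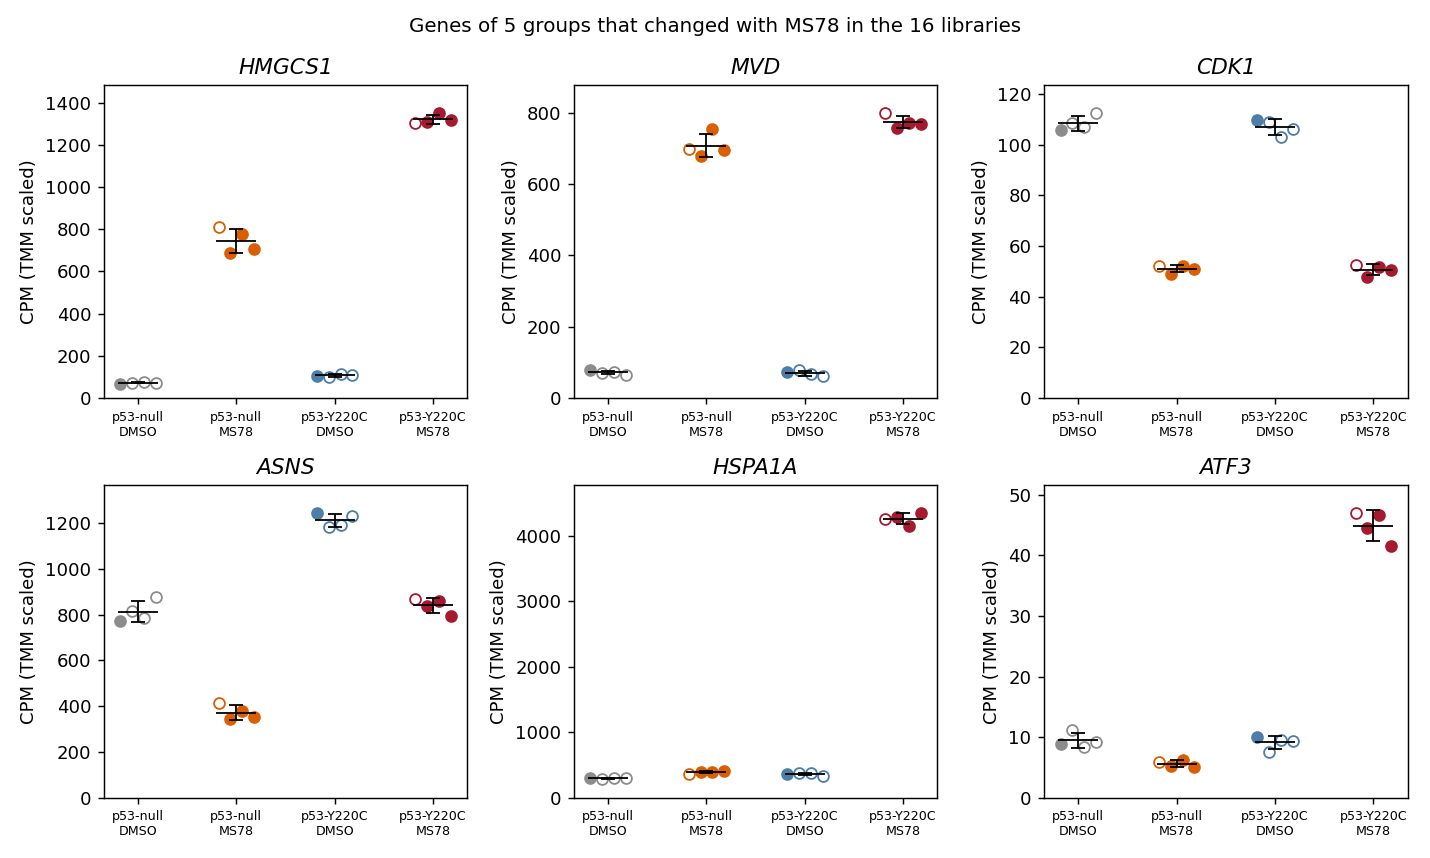
Levels of HMGCS1, MVD, CDK1, ASNS, HSPA1A and ATF3 in CPM, by group. Points are libraries (filled with PTPRC reads, open without) and bars are mean ± SD of 4 libraries, and HSPA1A rose from 362 to 4260 CPM with MS78 in p53-Y220C cells.

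Whether MS78 acted differently where p53 Y220C was present was tested as the difference between the responses of the lines. CDKN1A rose 2.02-fold more in p53-Y220C than in p53-null cells (log2 difference 1.01, SE 0.07, adjusted p = 7.07e-10, and 0.98 and 1.12 within the sets with and without PTPRC reads). Stress genes differed by more, HSPA6 by 6.06 (SE 0.57, adjusted p = 1.51e-07), FOS by 4.20 (SE 0.14, adjusted p = 9.29e-15), HSPA1A by 3.17 (SE 0.05) and ATF3 by 3.04 (SE 0.13, adjusted p = 1.19e-12). ATF3 fell in p53-null cells and rose in p53-Y220C cells, with log2 fold changes of -0.74 and 2.29.

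Past the threshold were 4197 of 15687 genes (26.8%), 2256 with a higher and 1941 with a lower response in p53-Y220C cells. At least 2-fold were 288 of them (146 and 142), and the median size was 0.369. Within the libraries with PTPRC reads 1870 genes were called and within those without 411 (300 higher and 111 lower). Of these 1731 and 400 were also called in the pooled test, with 0 in the opposite direction.

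Of 70 p53 targets 27 responded higher and 9 lower in p53-Y220C cells, the same counts adjusted over the list alone (median log2 difference 0.14, camera adjusted p = 0.000168, and 0.00103 and 0.000579 within the sets). PGF differed by 1.62 (SE 0.15), AEN, an apoptosis nuclease gene, by 1.24 (SE 0.11), and GADD45A, a growth arrest gene that stress factors also induce, by 1.23 (SE 0.07). SYTL1 differed by -1.12 (SE 0.29), a call lost within either set (0.191 and 0.105). Of 24 TRAIL pathway genes 10 responded higher and 0 lower, the same counts adjusted over the list alone (median 0.14, camera adjusted p = 0.00381, and 0.00636 and 0.0114 within the sets), with BIRC3 at 1.00 (SE 0.08). TNFRSF10A differed by 0.34 (SE 0.10, adjusted p = 0.0162) and TNFRSF10B by 0.47 (SE 0.06, adjusted p = 5.63e-06), both lost within the set without PTPRC reads (0.375 and 0.0535), where they were at 0.31 and 0.46. TNFRSF10D differed by 0.26 (SE 0.09, adjusted p = 0.0465). That call was kept when Null DMSO 2, Null DMSO 4, Null MS78 3 or Y220C DMSO 2 was left out and lost without any 1 of the other 12 libraries (0.0553 to 0.108). It was also lost with length-scaled TPM (0.124) and within either set (0.207 and 0.345). The adjusted p of MDM2 was 0.622 and that of TNFRSF10C 0.97. BCL2 family genes were not called (BAK1, HRK, MCL1 and PMAIP1 higher and BCL2L2, BMF and BNIP3 lower of 17, 4 and 3 adjusted over the list alone, camera adjusted p = 0.791). Their median was -0.08 and their mean -0.02 against an upward test direction. PMAIP1 differed by 0.98 (SE 0.11) and BMF, another pro-apoptotic member, by -0.88 (SE 0.09).

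Of 18 heat shock genes 17 responded higher and 0 lower, the same counts adjusted over the list alone (median 0.91, camera adjusted p = 1.53e-27). ER stress genes were higher in 19 of 25 cases and lower in 0 (20 and 0 adjusted over the list alone, camera adjusted p = 2.24e-16), with HSPA5 at 1.54 (SE 0.04, adjusted p = 9.92e-17). ATF4 targets were higher in 31 of 39 cases and lower in 1, DDIT4 (32 and 2 adjusted over the list alone, camera adjusted p = 1.25e-17), with DDIT3, the CHOP gene, at 1.78 (SE 0.10). Immediate early genes were higher in 18 of 28 cases and lower for DUSP6 and PHLDA1 (19 and 2 adjusted over the list alone, camera adjusted p = 4.97e-10), with FOSB at 4.10 (SE 0.22) and JUN at 2.76 (SE 0.07). NRF2 genes were higher in 14 of 22 cases, HMOX1 by 1.90 (SE 0.07), and lower in 2. These counts were the same adjusted over the list alone (camera adjusted p = 1.39e-07). NF-kB genes were higher in 11 of 16 cases and lower for CXCL2 and TNFAIP2 (12 and 2 adjusted over the list alone, camera adjusted p = 3.67e-05). PTGS2 was at 1.63 (SE 0.36), lost within the set without PTPRC reads (0.34), and TNFAIP3, a brake on NF-kB, at 1.43 (SE 0.14). Cholesterol genes were higher in 16 of 34 cases and lower for FDFT1, LSS and TM7SF2 (17 and 5 adjusted over the list alone, camera adjusted p = 3.67e-05). MYC targets were higher in 15 of 40 cases and lower for BOP1, NCL, NME1, NPM1 and TCOF1, the same counts adjusted over the list alone (camera adjusted p = 0.00194, but adjusted p = 0.259 with an estimated correlation). NME1 was at -1.11 (SE 0.11) and MYC itself at 1.05 (SE 0.07).

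Replication genes responded lower in 21 of 42 cases and higher for CDC6, DTL and SLBP (22 and 3 adjusted over the list alone, camera adjusted p = 2.34e-06, but adjusted p = 0.139 with an estimated correlation). Mitosis genes were lower in 21 of 48 cases and higher for ANLN and CKS2 (22 and 2 adjusted over the list alone, camera adjusted p = 6.39e-07). E2F2 was at -0.83 (SE 0.12) and MKI67 at -1.14 (SE 0.19), both lost within the set without PTPRC reads (0.0645 and 0.0535), while MCM5 was at -0.71 (SE 0.07) and CENPF, a kinetochore gene, at -0.87 (SE 0.11). Of 20 histone genes 6 responded higher and 1, H2BC21, lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.0331, but adjusted p = 0.139 with an estimated correlation). That call was lost without Null DMSO 3 (0.0729) or Y220C MS78 4 (0.0515) and within the set with PTPRC reads (0.0738). Of 13 mitochondrially encoded genes MT-ND1, MT-ND2, MT-ATP6, MT-ATP8 and MT-CYB were higher (6 adjusted over the list alone, camera adjusted p = 0.00381, but adjusted p = 0.308 with an estimated correlation). Of 61 ribosomal protein genes 4 were lower (2 adjusted over the list alone, median -0.08, camera adjusted p = 0.0211, but adjusted p = 0.699 with an estimated correlation), lost without Y220C DMSO 2 (0.115) or Y220C MS78 4 (0.218) and within the set without PTPRC reads, where it turned upward (0.253).

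The interferon list was not called (camera adjusted p = 0.0669) but passed without Null DMSO 4 (0.0364), Null MS78 4 (0.0301), Y220C DMSO 1 (0.028) or Y220C MS78 1 (0.0391), with a term for PTPRC reads (0.0445) and within the set without them (0.0259). Xenobiotic genes (0.0562) passed without any 1 of 7 libraries (0.0377 to 0.0496), namely Null DMSO 1 and 2, Null MS78 1 and 3, Y220C DMSO 3, and Y220C MS78 2 and 4, and also with the 1 CPM filter (0.0239) and a term for PTPRC reads (0.0439). Interferon and xenobiotic genes each passed as well with the replicate block across the lines within each treatment. Hypoxia genes (0.446) passed without Null DMSO 3 (0.0293). DNA damage genes were not called (7 higher and 11 lower of 72, 6 and 10 adjusted over the list alone, 0.227), nor were chromatin regulators (0.446), TGF-beta genes (0.698) or the markers of other cells (0.17 to 0.833). Autophagy genes were not called either (0.227), but passed under 3 of 25 alternatives, directional and mixed fry among them. Outside the lists, CRH, which encodes corticotropin-releasing hormone, responded lower by -2.19 (SE 0.47), SYT12 by -1.83 (SE 0.33), and the protocadherin genes PCDHA12 and PCDHGA5 by -2.37 (SE 0.49) and -1.82 (SE 0.46). None of these 4 genes passed within the set without PTPRC reads (0.282, 0.292, 0.217 and 0.0627), and PCDHGA5 did not within the other set (0.194). EGR4 and the phosphatase gene DUSP8 responded higher by 4.92 (SE 0.58) and 4.53 (SE 0.35).

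**Figure D4:**
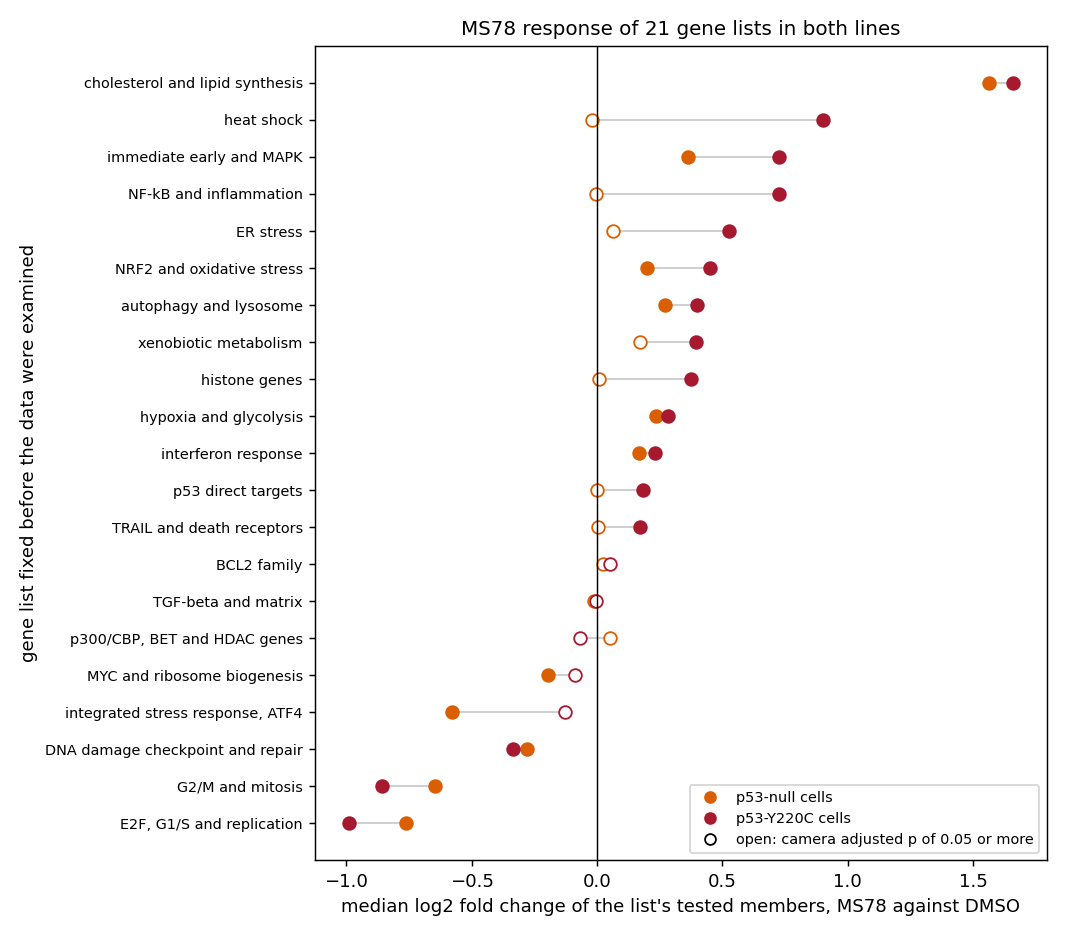
Median log2 fold change with MS78 of the tested members of 21 pathway and function lists, in p53-null cells (orange) and p53-Y220C cells (red). Filled symbols have a camera adjusted p under 0.05 and open symbols do not, and the heat shock list lies at -0.02 in p53-null and 0.90 in p53-Y220C cells.

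How far the lines responded alike was described by the correlation of log2 fold changes across the 15687 genes, which are not independent replicates. Pearson's r was 0.505 and Spearman's rho 0.434. In both lines more MS78 than DMSO libraries held leukocyte reads, so genes that came with these reads can raise r. Within the libraries with PTPRC reads r and rho were 0.155 and 0.32 over 16486 genes. Within those without they were 0.251 and 0.35 over 16362 genes. With a term for the libraries with PTPRC reads they were 0.432 and 0.439 over the 15687 genes. The lower r within either set comes from fewer samples and, since the filter was run again there, from other genes too, so it is not directly comparable. Genes that rose in both lines numbered 1479 (578.5 if the calls were independent) and genes that fell in both 1301 (491). Of the 336 genes called in opposite directions, 137 rose in p53-null cells and fell in p53-Y220C cells (546.7 if independent) and 199 did the reverse (519.6). All 336 were called for the difference.

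The untreated lines differed in many genes, and the comparison under DMSO gives the background against which the responses stand. CDKN1A was lower, at 37.4 ± 1.2 against 50.5 ± 2.7 CPM (SD, n = 4, log2 fold change -0.43, SE 0.05, adjusted p = 3.53e-07). TKTL1, a transketolase-like gene, had 0 reads in all 4 Y220C DMSO libraries and stood at 4.8 ± 0.35 CPM in Null DMSO, at least 33-fold lower against a floor of 3 reads per library. IGF2, which encodes insulin-like growth factor 2, stood at 2.01 ± 0.33 against 137 ± 5.5 CPM (log2 fold change -6.09, SE 0.09, adjusted p = 3.52e-20). EBF3, a transcription factor gene, had 39 to 56 reads per library in Y220C DMSO and 0 to 3 in Null DMSO.

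Past the threshold were 7875 of 15687 genes (50.2%), 3882 higher and 3993 lower in p53-Y220C cells, 1050 of them at least 2-fold (438 and 612), with a median size of 0.354. Within the libraries with PTPRC reads, which hold 1 DMSO library of each line, 3817 genes were called, and within those without, which hold 3, 6126. Of these 3681 and 5932 were also called in the pooled test, with 0 in the opposite direction. Line, G418 in the medium and transgene cannot be told apart in this comparison.

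RFPL4A and OLIG2 were also higher in p53-Y220C cells, by 4.81 (SE 0.25) and 4.61 (SE 0.42). These folds are uncertain, since Null DMSO libraries held 1 to 4 reads of RFPL4A and 0 to 6 of OLIG2. HSPA6 stood at 4.64 ± 0.9 against 0.19 ± 0.046 CPM (23.8-fold, with 4 to 6 reads per Null DMSO library). RARB, the retinoic acid receptor beta gene, had 0 to 3 reads per Y220C DMSO library, and CRH stood at 1.06 ± 0.6 against 53.2 ± 1.5 CPM. TNFRSF10B (0.25, SE 0.04, adjusted p = 4.02e-05) and TNFRSF10D (0.52, SE 0.07, adjusted p = 3.59e-06) were higher. MDM2 was lower (-0.27, SE 0.09, adjusted p = 0.0175), a call lost without Null DMSO 1 (0.0607), Y220C DMSO 1 (0.0681) or Y220C DMSO 2 (0.0595) and within the set without PTPRC reads (0.204). The adjusted p of TNFRSF10A was 0.35 and that of TNFRSF10C 0.455. Of 70 p53 targets 18 were higher and 24 lower, the same counts adjusted over the list alone (camera adjusted p = 0.554, median 0.01, mean -0.05). TLR3, an RNA sensor gene, was at 1.86 (SE 0.20) and PLK2, a polo-like kinase gene, at -1.63 (SE 0.07). TRAIL pathway genes were higher in 9 of 24 cases and lower for APAF1, BIRC3, TNFRSF1A and TRADD, the same counts adjusted over the list alone (camera adjusted p = 0.316).

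Replication genes were lower in 39 of 42 cases and higher in 1, CCNE1 (40 and 1 adjusted over the list alone, camera adjusted p = 2.57e-13, but adjusted p = 0.205 with an estimated correlation). RRM2, a ribonucleotide reductase gene, E2F1 and PCNA were at -0.91 (SE 0.04), -0.87 (SE 0.09) and -0.79 (SE 0.05). ATF4 targets were higher in 21 of 39 cases and lower in 10 (22 and 10 adjusted over the list alone, camera adjusted p = 0.00684, but adjusted p = 0.498 with an estimated correlation), with NUPR1 at 1.26 (SE 0.16). Autophagy genes were higher in 16 of 28 cases and lower in 7 (17 and 7 adjusted over the list alone, camera adjusted p = 0.0218, but adjusted p = 0.326 with an estimated correlation), with the autophagy receptor gene SQSTM1 2.43-fold higher. Of the 8 neural and HEK markers ELAVL3, NEFH, NEFL, NEFM and TUBB3, which encode a neuronal RNA-binding protein, neurofilament proteins and a tubulin, were lower and 0 were higher. These 5 were also called adjusted over the list alone (camera adjusted p = 0.032, but adjusted p = 0.283 with an estimated correlation). The list missed the threshold with the 1 CPM filter (0.0763) and within the set without PTPRC reads (0.0598). Ribosomal protein genes were higher in 19 of 61 cases and lower for RPL11 and RPL24 (19 and 1 adjusted over the list alone, median 0.08, camera adjusted p = 0.0218, but adjusted p = 0.798 with an estimated correlation). That call was lost without Y220C DMSO 2 (0.117).

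The remaining lists were not called. Heat shock genes were higher in 10 of 18 cases and lower for FKBP4, HSPB1 and HSPE1, the same counts adjusted over the list alone (camera adjusted p = 0.258), with HSPB1 at -0.88 (SE 0.05) and HSPA8 at 0.65 (SE 0.04). Cholesterol genes were higher in 17 of 34 cases and lower in 7 (camera adjusted p = 0.0959). TGF-beta genes were higher in 8 of 33 cases and lower in 17 (0.0959), with MMP1 at -1.93 (SE 0.12) and FN1, the fibronectin gene, at -1.76 (SE 0.07), and the list passed within the set with PTPRC reads (0.0184). NRF2 genes (0.0674) passed without Y220C DMSO 4 (0.042), and hypoxia genes (0.186) without Null DMSO 4 (0.0339) and within the set with PTPRC reads (0.0113). Interferon genes (7 higher and 10 lower of 30, 0.792) had a median of 0.05 and a mean of -0.06, and BST2, the tetherin gene, was 17.1-fold lower. Medians and means also differed in sign for MYC targets (0 and -0.05, 0.734), fibroblast markers (-0.04 and 0.14, 0.736) and chromatin regulators (-0.01 and 0.06, 0.515). Mitosis genes (12 higher and 18 lower of 48, 0.409) and DNA damage genes (16 and 30 of 72, 0.111) moved both ways.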

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

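The tests of leukocyte reads, of the libraries with PTPRC reads and of the lines under DMSO were chosen only after the result was seen, and the test of scaling before.

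Reads of leukocyte genes came with 8 of the 16 libraries rather than with line or treatment. Of the 12 tested members of the haematopoietic list without PTPRC, a list fixed before the data were examined, 10 were higher in DMSO replicate 1 than in MS78 replicate 1 of both lines, which argues against induction by MS78. Of the 58 rises of cholesterol list members over both lines, 58 were higher in MS78 replicate 1 than in DMSO replicate 1, which argues against exchanged labels of these libraries. Leukocyte RNA or reads may be the source, since 9 of the 12 haematopoietic list members were higher in the same 8 libraries. Other markers, chosen after the split was seen, went with them, with CCL5 at 8.79 to 27.8 CPM, GZMB at 16.7 to 23.5 CPM and CD74 at 8.97 to 18.9 CPM. Whether this RNA entered in culture, at library preparation or as reads of other samples stays open, and no other biological explanation was tested.

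The heat shock list responded to MS78 more in p53-Y220C than in p53-null cells (camera adjusted p = 1.53e-27). Within the sets with and without leukocyte reads the median log2 difference was 0.90 and 0.98, which excludes these libraries as the whole cause. In unscaled reads the median of all genes was -0.20 and that of the list 0.73, which excludes scaling. Line, G418 and p53 Y220C cannot be told apart as the source, since p53-null cells grown with G418 were not analysed here. Under DMSO 10 of the 18 members were already higher in p53-Y220C cells, but FKBP4, HSPB1 and HSPE1 were lower. The list was not called (camera adjusted p = 0.258) and 50.2% of all genes differed. HSPA6, which is not in the list, stood at 4.64 CPM in Y220C DMSO against 0.19 CPM in Null DMSO. It stays open whether this line was under stress before MS78. An effect of p53 Y220C on the stress response to MS78 may be 1 explanation and stays untested.

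Lists whose response differed between the lines, by the camera test of the difference, were cholesterol synthesis (adjusted p = 3.67e-05), E2F and replication (2.34e-06, but 0.139 with an estimated correlation), ER stress (2.24e-16), G2/M and mitosis (6.39e-07) and histone genes (0.0331, but 0.139 with an estimated correlation). So did immediate early genes (4.97e-10), ATF4 targets (1.25e-17), MYC targets (0.00194, but 0.259 with an estimated correlation), NF-kB genes (3.67e-05), NRF2 genes (1.39e-07) and p53 targets (0.000168). The same test passed TRAIL pathway genes (0.00381), mitochondrially encoded genes (0.00381, but 0.308 with an estimated correlation) and ribosomal protein genes (0.0211, but 0.699 with an estimated correlation). The call of ribosomal protein genes was also lost without Y220C DMSO 2 (0.115) or Y220C MS78 4 (0.218).

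Genes whose log2 response differed between the lines, by the test of the difference, are given with the difference, then the responses of p53-null and p53-Y220C cells in parentheses. Among genes fixed by name these were CDKN1A 1.01 (0.73, 1.74), TNFRSF10A 0.34 (0.24, 0.58), TNFRSF10B 0.47 (-0.13, 0.34) and TNFRSF10D 0.26 (0.71, 0.97). The call of TNFRSF10D was lost without any 1 of 12 of the 16 libraries (0.0553 to 0.108), with length-scaled TPM (0.124) and within the sets with and without PTPRC reads (0.207 and 0.345), with log2 differences of 0.24 and 0.38 there. The calls of TNFRSF10A and TNFRSF10B were lost within the set without PTPRC reads (0.375 and 0.0535), which holds fewer samples, with log2 differences of 0.31 and 0.46 there. Among the genes that the rule for named genes took for their large differences they were HSPA6 6.06 (0.63, 6.69), EGR4 4.92 (1.09, 6.01), DUSP8 4.53 (-0.68, 3.85), FOS 4.20 (0.75, 4.95) and FOSB 4.10 (0.56, 4.66). The negative ones were PCDHA12 -2.37 (0.85, -1.52), CRH -2.19 (0.13, -2.06), SYT12 -1.83 (1.38, -0.44) and PCDHGA5 -1.82 (0.25, -1.57). TKTL1, with 0 reads in Y220C DMSO, is not given a fold.

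Chaperone genes that differed were HSPA1A 3.17 (0.39, 3.56), HSPA1B 2.87 (0.42, 3.29), DNAJB1 2.01 (0.18, 2.20), HSPE1 0.90 (-0.03, 0.87) and HSPA5 1.54 (0, 1.54). HERPUD1 of the ER stress list differed by 1.5 (-0.23, 1.26). Stress genes were ATF3 3.04 (-0.74, 2.29), DDIT3 1.78 (-0.69, 1.09), PPP1R15A 1.55 (0.08, 1.63), JUN 2.76 (-0.23, 2.53), HMOX1 1.90 (0.55, 2.45) and SLC7A11 1.30 (-1.14, 0.16). Genes of the p53 list were PGF 1.62 (0.01, 1.63), AEN 1.24 (-0.43, 0.81), GADD45A 1.23 (-0.36, 0.88) and SYTL1 -1.12 (-0.01, -1.13). Cell death genes were BIRC3 1.00 (-0.01, 1.00), TRAF2 0.44 (-0.27, 0.16), CASP9 0.43 (0.17, 0.59), PMAIP1 0.98 (-0.59, 0.39) and BMF -0.88 (0.85, -0.03), and the calls of TRAF2 and CASP9 were lost within the libraries without PTPRC reads (0.117 and 0.0992), with log2 differences of 0.56 and 0.52 there. Lipid genes were ELOVL6 0.73 (0.57, 1.30) and FASN 0.71 (2.55, 3.26). Cell cycle genes were E2F2 -0.83 (-0.99, -1.82), MCM5 -0.71 (-0.80, -1.51), MKI67 -1.14 (-0.35, -1.49) and CENPF -0.87 (-0.45, -1.32). Others were PTGS2 1.63 (0.26, 1.89), TNFAIP3 1.43 (-0.04, 1.39), NME1 -1.11 (-0.32, -1.43), MYC 1.05 (-0.25, 0.80) and HDAC9 0.82 (1.38, 2.20).

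A library far from the other 3 of its group was found in 25 of 552 groups tested, where chance gives about 1 in 20 (27.6). In Null DMSO these were replicate 1 for HSPA6 (0.257 CPM) and LIF (15.3 CPM), replicate 3 for EGR4 (0.172 CPM), MXD3 (14.2 CPM) and PLD5 (6.64 CPM), and replicate 4 for depth (24.7 M reads). In Null MS78 they were replicate 1 for MT1X (45.1 CPM) and the mitochondrial share (4.04%), replicate 2 for EXO1 (12.7 CPM), replicate 3 for RARB (3.73 CPM) and ABCC2 (1.45 CPM), and replicate 4 for OSGIN1 (26.0 CPM). In Y220C DMSO replicate 1 stood apart for FASN (712 CPM), TNFAIP3 (8.70 CPM) and HAS2 (0.171 CPM). There replicate 2 did so for TNFRSF10D (25.5 CPM), EXO1 (15.9 CPM), MXD3 (12.9 CPM) and CA8 (3.09 CPM), and replicate 4 for BIRC3 (51.2 CPM) and PMAIP1 (21.2 CPM). In Y220C MS78 replicate 1 stood apart for NEU1 (269 CPM) and PLD5 (0.0982 CPM), replicate 2 for HRK (12.1 CPM) and replicate 3 for CDKN1A (115 CPM, the others 127 to 129 CPM).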

How the results depend on the processing

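The term for libraries with PTPRC reads, the 2 sets with and without them and the block across the lines were chosen only after the result was seen, and the other alternatives before. Within each set of 8, 1 treatment group of each line has a single library, which is assumed to vary like the others. Depth limits genes near the floor of 3 reads, such as EGR4 and TKTL1, whose folds are uncertain.

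Counts of called genes were between 4264 and 4504 for MS78 in p53-null cells, 7273 and 7565 in p53-Y220C cells, 4010 and 4254 for the difference and 7645 and 7933 for the lines with RLE, DESeq2, limma-voom, no filter and the 1 CPM filter. Leaving out 1 library gave 3688 to 4054, 6966 to 7334, 3685 to 4250 and 7270 to 7798. A fit of the compared groups alone gave 4651, 7047 and 7526 for the 3 comparisons of 2 groups. The term for PTPRC reads gave 4024, 7260, 4225 and 7946, of which 3807, 6986, 4124 and 7819 were also called without it and had the same direction. With length-scaled TPM the counts fell to 2848 for MS78 in p53-null cells, 6005 in p53-Y220C cells, 2751 for the difference and 6158 for the lines, and the cause was not tested. Within the libraries with PTPRC reads they were 2346 in p53-null cells, 1870 for the difference and 3817 for the lines. Within those without they were 1070 in p53-null cells, 3490 in p53-Y220C cells and 411 for the difference. Both sets hold fewer samples. A 2-fold threshold left 213, 696, 288 and 1050, since it is stricter by construction. With it 162 of 213 changes in p53-null cells were rises, and within the libraries without PTPRC reads 300 of 411 differences were positive.

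The replicate number as a block gave 4251, 7442, 4060 and 7774. In p53-null cells deviations from the group means of same-numbered DMSO and MS78 libraries correlated between -0.502 and -0.042. In p53-Y220C cells these correlations were between -0.496 and -0.067. Same-numbered DMSO and MS78 libraries always differed in whether they held leukocyte reads, which can make such correlations negative. They therefore do not decide whether numbers pair DMSO with MS78 samples of a line. The block ended 1 list call, that of xenobiotic genes in p53-Y220C cells (0.0502). Across the lines the deviations of same-numbered libraries correlated between -0.057 and 0.452 under DMSO and between 0.15 and 0.531 under MS78. Every same-numbered pair thus deviated together under MS78, but not every pair did under DMSO. Pairs with different numbers could do so as well, such as Null MS78 3 with Y220C MS78 2 (0.215). Reads of the leukocyte gene GNLY separated replicates 2 and 3 from replicate 4 in both lines under MS78. They were 890, 905 and 154 in Null MS78 2, 3 and 4. In the same replicates of Y220C MS78 they were 796, 824 and 144. Same-numbered libraries of the 2 lines also matched in whether they held leukocyte reads, which can make them deviate together. Whether numbers pair samples of the 2 lines is therefore not settled by these values. A block across the lines, within each treatment, gave 4607 genes for the difference and 8201 for the lines. It ended no call of a gene or list, and interferon (0.0331) and xenobiotic genes (0.0476) passed for the difference.

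The 200 results for genes followed under the alternatives kept direction and side of the threshold under RLE, DESeq2, limma-voom, no filter, the 1 CPM filter and the block, and 150 of 150 did so in fits of the compared groups alone. Calls ended for 4 with length-scaled TPM, for 1 with the term for PTPRC reads, for 11 within the libraries with them, for 28 within those without, and in 22 of the 2000 results with 1 library left out. No gene changed direction where it was called, though MDM2, TNFRSF10A and TNFRSF10C changed sign in comparisons that did not call them, within a set or with 1 library left out. The median of all genes stayed between -0.026 and 0.013. The cause was not tested for the length-scaled TPM values.

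Of 108 list results 91 kept their side of the threshold with an estimated correlation and 17 calls ended, by a test that allows for members varying together. With the 1 CPM filter 101 of 104 were on the same side, and of 108 each there were 103 with the term for PTPRC reads, 102 within the libraries with them and 101 within those without. With 1 library left out 1052 were, while 10 calls ended and 18 new ones were made. Fry tests whether the genes of a list change on balance in 1 direction (directional) or in either (mixed) and does not compare them with other genes, so its calls answer another question than those of camera. Directional fry called 30 lists that camera did not and left out 3 that camera called, with 74 on the same side, and for mixed fry these were 49, 3 and 56. Directional fry also reversed chromatin regulators in p53-Y220C cells (adjusted p = 0.00184, upward, where camera gave a downward direction without a call), and the cause was not tested. For the difference in DNA damage genes, which camera did not call, fry gave 0.0481 (directional) and 8.57e-19 (mixed), which differs by the construction of the tests. Ribosomal protein genes reversed within the libraries without PTPRC reads, upward in p53-Y220C cells (0.00231) and for the difference (0.253), and the cause was not tested.

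The correlation of responses between the lines was 0.505 with RLE, 0.556 with the 1 CPM filter, 0.573 over genes called in either line, 0.432 with the term for PTPRC reads, and 0.155 and 0.251 within the sets with and without them. The filter and the restriction to called genes use fewer genes by construction. The sets hold fewer samples and more tested genes (16486 and 16362). With the term Pearson's r fell while Spearman's rho was 0.439, against 0.434 without it. Genes that came with the leukocyte reads may contribute to that fall, which was not tested.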

Other observations

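The tests on other splits and arrangements of the samples and those that left out 1 kind of TRAIL list member were chosen only after the result was seen, and the other tests on reduced lists before.

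ATF4 targets fell as a list in p53-null cells and were not called in p53-Y220C cells, where 20 of 39 fell and 11 rose. There ATF3, DDIT3 and PPP1R15A rose and SLC7A11, which fell in p53-null cells, was at 0.16. The cholesterol rise and the fall of mitosis and replication genes were present in both lines. Their size differed between the lines for cholesterol and mitosis genes, while the difference for replication genes was not called with an estimated correlation (0.139).

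The larger response of p53 targets in p53-Y220C cells could come from members that also belong to other lists, those of stress and inflammation among them. This was tested by leaving out every member that any other fixed list holds. The 56 members left of 70 still passed for the difference (19 higher and 9 lower, median 0.12, camera adjusted p = 0.00401, and adjusted p = 0.00911 with an estimated correlation), so shared members are excluded as the whole cause. Whether a p53-directed part of the response exists stays open, since the members left may also respond to stress and the lines also differ in G418. MDM2 stood at 13.2 CPM in both groups of p53-Y220C cells. CDKN1A also rose in p53-null cells, from 50.5 to 83.6 CPM, though less than in p53-Y220C cells (37.4 to 125 CPM). For TRAIL pathway genes, the 15 members left of 24 without those shared with other lists and those called for the term for PTPRC reads no longer passed (6 higher and 0 lower, median 0.03, camera adjusted p = 0.0674). Without the shared members alone the 16 left did not pass (0.0781), and without those called for the term alone the 23 left did (0.00323). Genes that came with the leukocyte reads are therefore excluded as the cause of that call, and shared members may account for it, though a shorter list also has less power.

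Whether chance can give as many called genes was tested by other splits of the same samples. For MS78 in p53-null cells 1 of 35 splits, the real one, gave as many as 4402 genes, and the highest other gave 7, which was the split that followed the leukocyte reads. For MS78 in p53-Y220C cells 1 of 35 gave as many as 7611, and the highest other gave 1. For the lines under DMSO 1 of 35 gave as many as 7875, and the highest other gave 439. In each of the 3, the real split gave the most genes, which is the smallest share that 35 splits allow. The other splits mixed the groups and put any effect into the spread, so the size of their counts decides little. Chance labelling of these samples is thus improbable at 1 of 35. Differences between cultures are not covered, since replicates may be technical. For the difference between the lines 2 of 100 splits gave as many as 4197, and the highest other gave 5708. The 6 drawn splits that kept or reversed the treatment labels within p53-Y220C cells gave 2901 to 5708 and the others at most 152. MS78 changed genes in p53-Y220C cells whether or not the lines respond alike, so treatment labels within a line cannot be exchanged to test the difference, and these splits decide nothing about it. A test that keeps the effects of line and treatment was therefore run. It rearranged what a sum of these 2 effects left over in log2 CPM, and 1 of 100 arrangements, the real one, gave as many as 4199 genes with limma, and the highest other gave 1951. The real count was thus the highest, but this test treats the samples as exchangeable. Same-numbered MS78 libraries of the 2 lines deviated together (correlations of 0.15 to 0.531), and leukocyte reads came with some libraries only. Chance is therefore improbable for the difference only as far as the samples vary independently.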
